A study of Populus ussuriensis with 9 samples.

How the data were processed

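RNA was sequenced from 9 libraries of Populus ussuriensis, a poplar grown in vitro, on an Illumina HiSeq instrument per the labels. Per the labels' protocols, plants were 21 days old and kept at 25 °C with 16 h of light and 8 h of dark. They were sprayed with a spore suspension of M. larici-populina, the fungus of poplar leaf rust, at about 100000 spores per mL, bagged in the dark for 24 h and sampled on day 2. The labels describe the material in more than a single way: as a stem tip with 2 pieces of leaf, and as leaf. RNA was extracted with CTAB, and 2 µg of total RNA went into each library with a TruSeq RNA kit. The groups were taken from the genotype label: wild type (WT), and the lines OE14 and OE18 of a plant overexpressing LbDREB6, a gene named as a member of the DREB family of transcription factors. Each group had 3 libraries, all of them inoculated. A water-sprayed control is named in the treatment protocol, but no water-sprayed library was analysed here, so no comparison below measures the response to the fungus. The labels do not say whether the 3 libraries of a group came from separate plants or cultures. P-values therefore measure only the spread between these libraries, which may be technical. Replicate numbers follow accession order and only name the libraries.

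The authors deposited 1 table per library with raw read counts per gene, per the file headers, and these counts were the values tested. The same tables hold FPKM values and a normalized signal, both computed by the authors. The deposited FPKM was 0 in 100% of genes with a count of 0. The deposited normalized signal was the count times a library factor for 71.1% to 73.9% of genes (within 0.1%) and lower for the others. Its factors ran from 0.788 in WT replicate 1, the library with the most counts, to 1.09 in OE18 replicate 2. FPKM and normalized signal entered no test. TopHat2 2.1.1 and HTSeq 0.6.0 are named in the submitters' processing notes, without their role. The genome build is not given in the sources used here. Gene identifiers carry the ending v3.0 of Populus trichocarpa gene models, and coordinates below are those of the files. Reads of Populus ussuriensis that differ from the reference can be lost in mapping, which lowers a count without any change in transcript level. The strand setting of the counting is not stated, so reads of overlapping or antisense genes may be counted together, and how reads shared by near-identical copies were counted is not stated either. Each table lists 39808 genes, of which 39570 are v3.0 gene models and 238 are loci added by the submitters. Every row carries a gene identifier.

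The total count per library ran from 12731324 to 17467974. Counts were tested in R 4.3.3 with edgeR 4.0.16. Genes were kept by filterByExpr with the group factor (minimum count of 10, minimum total of 15), which left 24941 genes, 188 of them added loci; 7566 listed genes had no count in any library. Libraries were scaled by TMM, with factors from 0.971 to 1.021. All 9 libraries entered a single quasi-likelihood fit (glmQLFit, glmQLFTest) with a mean per group, so that the groups shared an estimate of the spread. The biological coefficient of variation was 12.1%. The contrasts were OE14 against WT, OE18 against WT, the mean of both lines against WT and OE18 against OE14. A gene was called at a Benjamini-Hochberg adjusted p under 0.05, two-sided, over the genes tested. Standard errors of log2 fold changes were obtained as the fold change over the square root of the F statistic and are approximate. CPM values use TMM-scaled library sizes, and log2 CPM uses a prior count of 2. Where a group had no count, the fold was given as a bound from a floor of 3 counts over the group. Floors cover counting error only, and the binomial intervals given for shares of genes treat genes as independent draws. Counts were simulated for OE14 against WT over 24941 genes, with 100 genes changed by 1 and 100 by 2 on the log2 scale. The changed genes were drawn from those with a mean of at least 5 CPM, so recovery below that level was not measured. The test recovered 91% and 100% of the changed genes, and 5% of its calls were false. For OE18 against WT it recovered 93% and 98%, and for OE18 against OE14 93% and 100%, with 5.9% and 8.5% of false calls.

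The tables pair identifiers with no gene name or description, and no annotation was used here. The 29 gene lists fixed before the data were examined (defence, hormone, stress and tissue marker genes, picked by description) could therefore not be tested, and the row of LbDREB6, if any, could not be looked up. For this case the naming rule, also fixed before the data were examined, allows the 2 identifiers that rose and the 2 that fell most in both lines. They were taken from genes called in both lines with the same sign, whose 6 transgenic libraries all lay outside the range of the WT libraries and whose higher group mean was at least 5 CPM, ranked by the smaller of the 2 absolute fold changes. Gene groups were described instead by position and class, which were chosen after the values were seen.

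Fold changes were scanned along chromosomes 1 to 19 with Python 3.11.15 and numpy 2.4.6 over the 19679 tested genes with an average log2 CPM above 2. Circular binary segmentation was applied to fold changes clipped at 1.5 around their median, with a minimum of 20 genes per segment. A segment was kept when its statistic exceeded the highest value of 200 permutations of gene order over the whole genome and its median differed from that of all genes by at least 0.25 (log2). Permuting single genes treats neighbours as independent, so this bound may be too low where neighbours move together. On a shuffled gene order of OE18 against WT with 4 shifted segments placed in it, 4 were found, with 0 false segments and edges at most 3 genes off. That check used fewer permutations and, with its shuffled order, did not test the effect of neighbours that move together. Genes were described as on in a group when every library reached 5 CPM and as off when every library stayed under 0.5 CPM. Shares of calls were compared by Fisher's exact test, two-sided, with scipy 1.17.1; neighbouring genes are not independent, so such p-values are too small where calls cluster. Alternatives were other scalings (DESeq2 size factors, upper quartile), other filters, the DESeq2 1.42.0 Wald test, limma-voom (limma 3.58.1), a fit on only the groups compared, an added 2-fold threshold, and leaving out each library. Refits without the genes of the shifted regions and other limits for on and off were added after the data were seen. No 2 libraries agreed within sampling noise: chi-square per degree of freedom over genes ran from 4.35 to 21.54 within groups.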

Results

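The deposited tables hold read counts of 39808 poplar genes in 9 libraries of rust-inoculated plants: 3 of WT, 3 of the LbDREB6-overexpressing line OE14 and 3 of the overexpressing line OE18. Total counts were 17467974, 12747484 and 13009275 in WT, 14347700, 14336368 and 13370602 in OE14, and 13172653, 12731324 and 13665269 in OE18. Between 28822 and 29254 genes had a count in a library, and the 10 most abundant genes took 2.67% to 3.51% of the counts. Libraries of a group resembled each other more than those of other groups. The mean Pearson correlation of log2 CPM across genes was 0.983 within WT, 0.986 within OE14 and 0.979 within OE18, against 0.962 between WT and OE14, 0.943 between WT and OE18 and 0.938 between the lines. Genes are not independent replicates in these correlations. The first principal component held 47.1% of the variance and set OE18 apart from the other groups, and the second, with 23.5%, parted WT from OE14. Within OE18, replicate 1 stood apart on the third component, which held 8.2%.

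**Figure D1:**
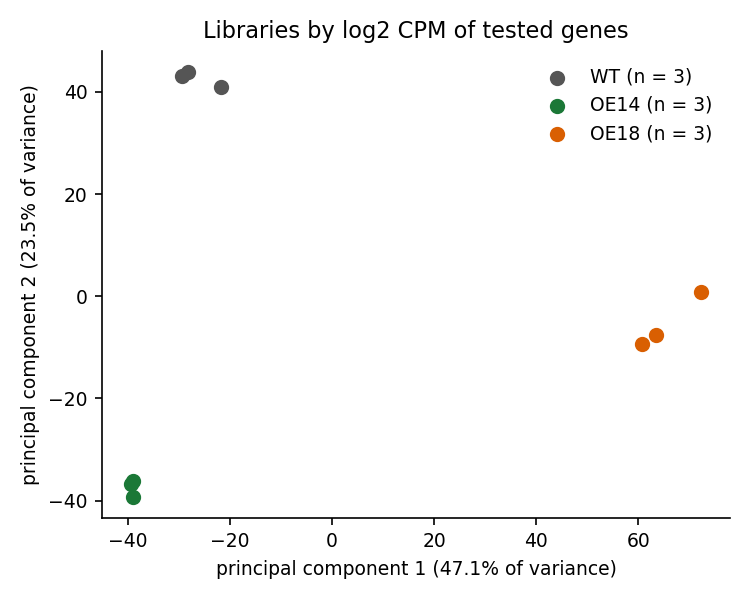
Each point is a library, placed by its scores on the first (47.1% of variance, horizontal) and second (23.5%, vertical) principal components of log2 CPM; colours mark the 3 groups of 3 libraries. OE18 lies apart from WT and OE14 on the horizontal axis, and WT lies apart from OE14 on the vertical axis.

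The comparison of OE14 with WT asks which transcripts differ between a transgenic line and wild type, 2 days after inoculation. The genes that moved together most visibly lay side by side. Over the first end of chromosome 5, from position 2360 to 4558913, 252 of 255 expressed genes were lower in OE14 than in WT, with a median log2 fold change of -0.98, a ratio of 0.51. Over the first end of chromosome 18, from 3527 to 1983321, 122 of 124 expressed genes were higher in OE14, with a median log2 fold change of 0.58, a ratio of 1.49. Smaller shifts covered 28 genes of chromosome 7 (8989312 to 9586857, median -0.55, 28 of 28 lower) and 213 genes at the first end of chromosome 13 (30889 to 2670957, median 0.37, 198 of 213 higher).

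The segment statistics were 45.0 for chromosome 5, 18.9 for chromosome 18, 16.7 for chromosome 13 and 9.2 for chromosome 7, where the highest value over 200 permutations of gene order was 6.22. The shift was the same size in each OE14 library. Relative to each gene's mean over the 9 libraries, the median deviation in the chromosome 5 region was -0.619 ± 0.006 (SD, n = 3) in OE14, 0.322 ± 0.019 (SD, n = 3) in WT and 0.315 ± 0.007 (SD, n = 3) in OE18. In the chromosome 18 region it was 0.384 ± 0.010 (SD, n = 3) in OE14, -0.189 ± 0.025 (SD, n = 3) in WT and -0.194 ± 0.014 (SD, n = 3) in OE18. The 3 OE14 libraries overlapped with neither other group in these 2 regions; an exact permutation test of 3 libraries against 3 cannot give a p below 0.1. The positions of the regions were chosen from the fold changes themselves.

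**Figure D2:**
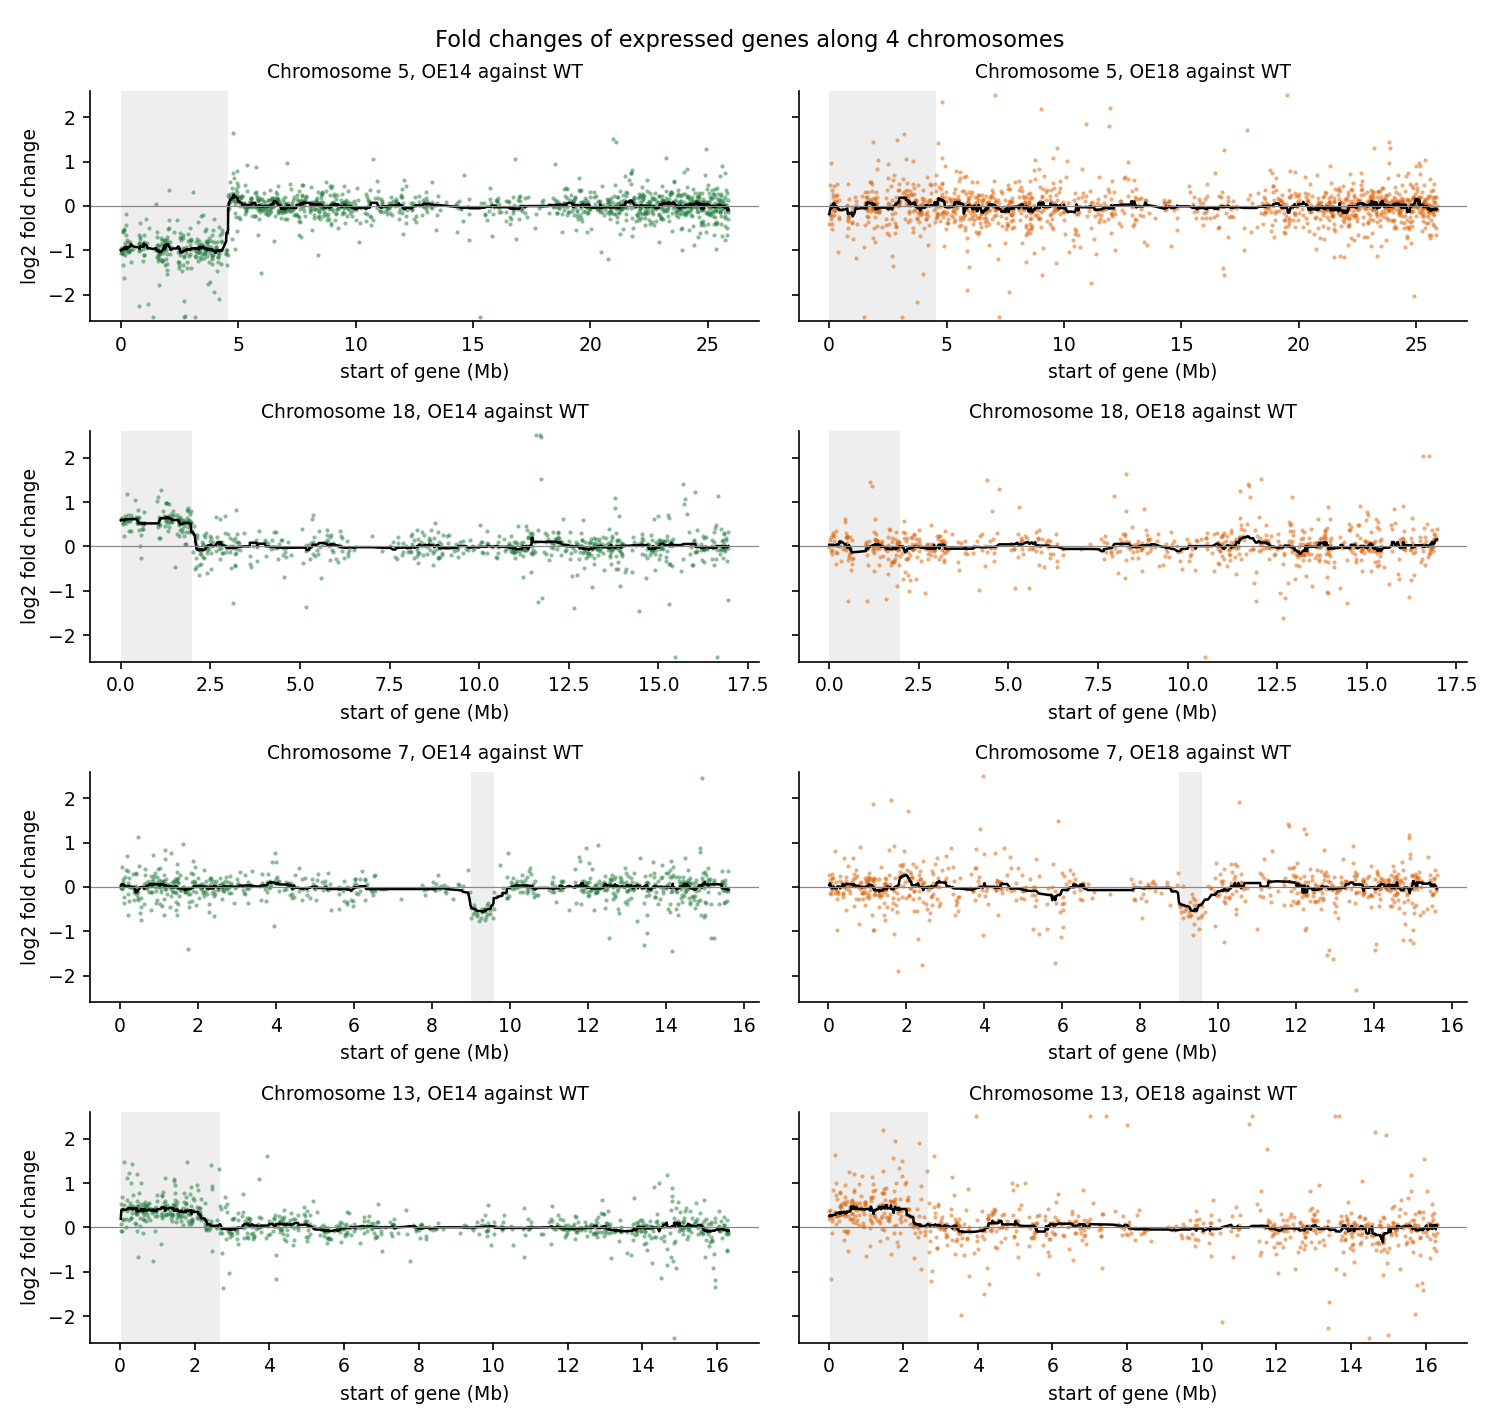
Log2 fold change (vertical) of each tested gene with an average log2 CPM above 2 against the start of the gene in Mb (horizontal) on chromosomes 5, 18, 7 and 13, for OE14 against WT (left) and OE18 against WT (right). The line is a running median over 25 genes, points beyond 2.5 are drawn at 2.5, and the shaded spans are the shifted regions. The chromosome 5 and chromosome 18 spans are shifted in OE14 (medians -0.98 and 0.58) and lie at 0.00 and -0.01 in OE18, while the chromosome 7 and 13 spans are shifted in both lines.

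Over all genes, edgeR's quasi-likelihood test called 1915 of 24941 genes (7.7%) in OE14 against WT, 911 higher and 1004 lower, and 338 of the higher and 443 of the lower ones changed at least 2-fold. The chromosome 5 region held 247 of the 1004 lower calls (24.6%), the chromosome 18 region 91 of the 911 higher calls (10.0%) and the chromosome 13 region 69 (7.6%). Outside the shifted regions, 750 genes were higher and 732 lower. By whole chromosomes, lower calls made up 17.3% of the tested genes of chromosome 5 against 3.1% elsewhere (Fisher's exact test, adjusted p = 2.61e-104 over 152 tests), and higher calls 14.3% of those of chromosome 18 against 3.2% elsewhere (adjusted p = 7.14e-41). The count of calls was 1261 without OE14 replicate 1 and 1240 without OE14 replicate 2.

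Outside the regions, genes called with at least a 2-fold change often lay next to each other: 76 neighbouring pairs of the same direction were found among 635 such genes, where 1000 permutations of gene order gave a mean of 8.1 and at most 20. The p of 0.001 is the smallest that these permutations can give. Runs of at least 4 such neighbours in OE14 against WT were higher at 5 genes of chromosome 11 (2851211 to 3069433, median log2 fold change 3.30), at 4 genes of chromosome 6 (27283823 to 27459671, median 5.10), at 5 genes of scaffold_20 (136612 to 606296, median 4.19) and at 4 genes of chromosome 1 (37518818 to 37838955, median 2.41). A run of 4 genes of scaffold_25 (515311 to 552407, median -1.44) was lower. Genes on scaffolds, sequence not placed on a chromosome, were called more often than other genes, at 19.1% of 602 against 7.4% (Fisher's exact test, adjusted p = 1.19e-18 over 28 tests), 58 of them higher and 57 lower. Loci added by the submitters were called at 8% of 188, against 7.7% of the other genes (adjusted p = 0.958).

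The comparison of OE18 with WT asks the same question for the other line. The largest block of neighbouring genes that moved was the first end of chromosome 13, where the segment from 103635 to 2172830 held 180 expressed genes with a median log2 fold change of 0.41, a ratio of 1.33, and 162 of them were higher in OE18. A segment of 29 genes on chromosome 7, from 8989312 to 9656890, had a median of -0.53, a ratio of 0.69, with 28 genes lower. On chromosome 2, from 5493489 to 5771619, 19 of 20 genes were lower, with a median of -0.61 and a wide spread between genes (interquartile range 0.665 against 0.361 for other genes). The chromosome 5 and 18 regions that were shifted in OE14 had medians of 0.00 and -0.01 in OE18 against WT.

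The segment statistics were 12.3, 6.7 and 6.4 for chromosomes 13, 2 and 7, against a highest permuted value of 5.94. The values of chromosomes 2 and 7 lay close above that bound, which takes neighbouring genes as independent. In the chromosome 7 and 13 regions the 2 lines had close values and WT differed from both. The median deviation on chromosome 7 was 0.376 ± 0.088 (SD, n = 3) in WT, -0.189 ± 0.016 (SD, n = 3) in OE14 and -0.163 ± 0.026 (SD, n = 3) in OE18. On chromosome 13 it was 0.127 ± 0.018 (SD, n = 3) in OE14 and 0.120 ± 0.027 (SD, n = 3) in OE18. The 3 WT libraries were far apart there, at -0.238, -0.059 and -0.433, with an SD of 0.187 (n = 3), and none overlapped with the lines. On chromosome 2, OE18 stood at -0.378 ± 0.051 (SD, n = 3), below WT at 0.188 ± 0.069 (SD, n = 3) and OE14 at 0.190 ± 0.037 (SD, n = 3).

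**Figure D3:**
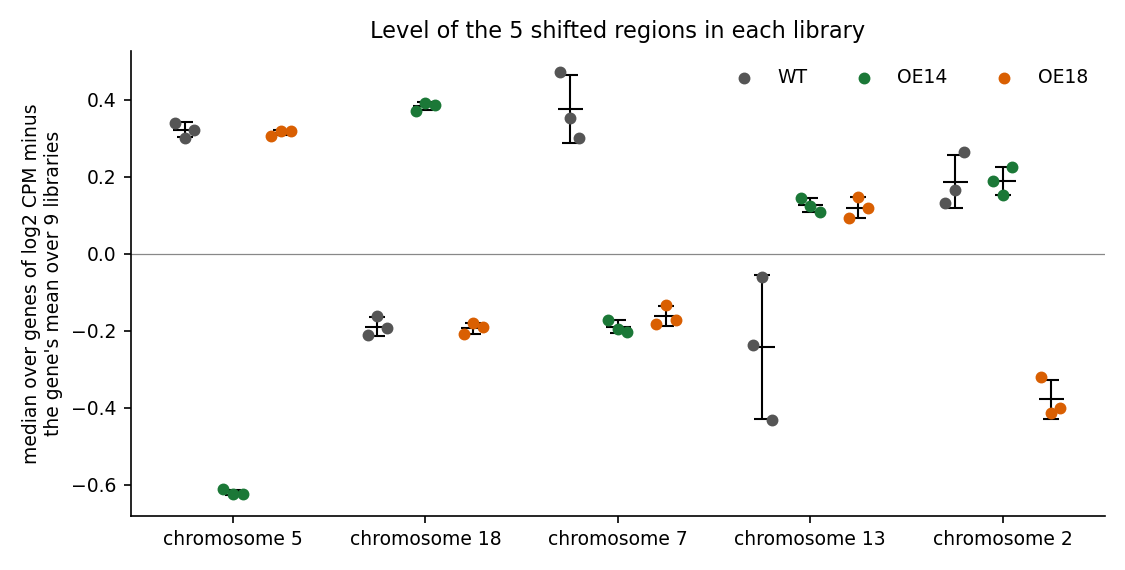
Level of each shifted region in each library, as the median over its genes of log2 CPM minus the gene's mean over the 9 libraries (vertical), for the 5 regions (horizontal). Points are libraries, coloured by group, and bars give the mean and SD of 3 libraries. OE14 stands apart in the chromosome 5 (-0.619) and 18 (0.384) regions, OE18 in the chromosome 2 region (-0.378), and WT in the chromosome 7 (0.376) and 13 regions, the last with WT libraries at -0.238, -0.059 and -0.433.

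In OE18 against WT, edgeR's quasi-likelihood test called 5347 of 24941 genes (21.4%), 2641 higher and 2706 lower, and 931 of the higher and 796 of the lower ones changed at least 2-fold. The shifted regions held few of these: 2491 higher and 2608 lower calls lay outside them. Among genes of chromosome 13, 17.4% were called higher against 10.3% elsewhere (Fisher's exact test, adjusted p = 1.45e-09 over 152 tests). The most abundant transcripts were called more often than others. Of the 100 genes with the highest mean level, 52 were called, 21 higher and 31 lower, a share of 52% against 21.3% of other genes (adjusted p = 1.61e-10 over 28 tests). Abundant genes have more counts, and smaller changes can be called in them. In OE14 against WT 9 of the same 100 genes were called, 1 higher and 8 lower (9% against 7.7%, adjusted p = 0.773). Scaffold genes were called at 29.9% against 21.2% (adjusted p = 4.53e-06).

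Runs of neighbouring 2-fold calls also occurred in OE18, with 167 pairs against a permuted mean of 54.9 and a highest value of 81 (p = 0.001 in 1000 permutations, the smallest they can give). A run of 6 genes of chromosome 12 (739831 to 965929) was lower, with log2 fold changes from -7.96 to -1.12 and a median of -5.13. A run of 6 genes of chromosome 1 (40412588 to 40618695) was higher, with a median of 3.29, and another of 4 genes of chromosome 1 (33296593 to 33318286) had a median of 1.52. The 4 genes of chromosome 1 from 37518818 to 37838955 that were higher in OE14 were higher in OE18 too, with a median of 2.54. The 4 genes of scaffold_25 from 515311 to 552407 were lower again, with a median of -2.91.

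The mean of both lines against WT asks how the overexpressing plants differ from WT on average. A change in a single line can be enough for a call, so a call does not show that both lines share it. Under the naming rule, the 2 genes that rose most in both lines were Potri.003G190600.v3.0 on chromosome 3 (19522303 to 19524300, plus strand) and Potri.001G426200.v3.0 on chromosome 1 (45208947 to 45214205, minus strand). A run of 4 genes of scaffold_20 (291060 to 606296) held a larger rise in the mean of both lines, with log2 fold changes from 2.09 to 8.63. Potri.003G190600.v3.0 had 0.806 ± 0.476 CPM (SD, n = 3) in WT, 27.9 ± 3.75 CPM (SD, n = 3) in OE14 and 51.3 ± 15.8 CPM (SD, n = 3) in OE18. Its log2 fold change was 5.02 (SE 0.346) in OE14 and 5.90 (SE 0.337) in OE18, with adjusted p = 6.09e-06 and 1.11e-06 in edgeR's quasi-likelihood test. Potri.001G426200.v3.0 had 0.401 ± 0.280 CPM (SD, n = 3) in WT, 9.64 ± 0.585 CPM (SD, n = 3) in OE14 and 10.7 ± 1.31 CPM (SD, n = 3) in OE18, and rose by 4.58 (SE 0.290) and 4.73 (SE 0.289) on the log2 scale, with edgeR adjusted p = 3.18e-06 and 1.56e-06. In WT these genes rested on 37 and 17 counts over the 3 libraries.

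The 2 genes that fell most under the naming rule had no count in any of the 6 transgenic libraries. Potri.019G022000.v3.0 on chromosome 19 (2494384 to 2496394, plus strand) had 258, 198 and 213 counts in WT, or 15.5 ± 0.754 CPM (SD, n = 3), and was at least 218-fold lower in OE14 and at least 205-fold lower in OE18, taking a floor of 3 counts over each group. Potri.T013300.v3.0 on scaffold_25 (236351 to 505740, minus strand) had 143, 98 and 106 counts in WT, or 8.00 ± 0.293 CPM (SD, n = 3), and was at least 112-fold and 106-fold lower. Its adjusted p was 3.23e-05 in OE14 and 2.12e-05 in OE18, and that of Potri.019G022000.v3.0 was 8.89e-06 and 6e-06 (edgeR). In all, 327 genes that rose and 307 that fell met the same rule.

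For the mean of both lines, edgeR's quasi-likelihood test called 3314 genes (13.3%), 1539 higher and 1775 lower, and 421 and 428 of them changed at least 2-fold. The chromosome 5 region, shifted in OE14 alone, gave 193 of the 1775 lower calls (10.9%), and the chromosome 13 region 114 of the 1539 higher calls (7.4%). Scaffold genes were called at 23.9% against 13% (Fisher's exact test, adjusted p = 1.25e-11 over 28 tests), and 37 of the 100 most abundant genes were called, 9 higher and 28 lower. When each group was set against the mean of the other groups, WT differed in 3314 genes, OE14 in 3221 and OE18 in 6620. The count for WT fell to 2035 without WT replicate 2 and to 2199 without WT replicate 3.

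**Figure D4:**
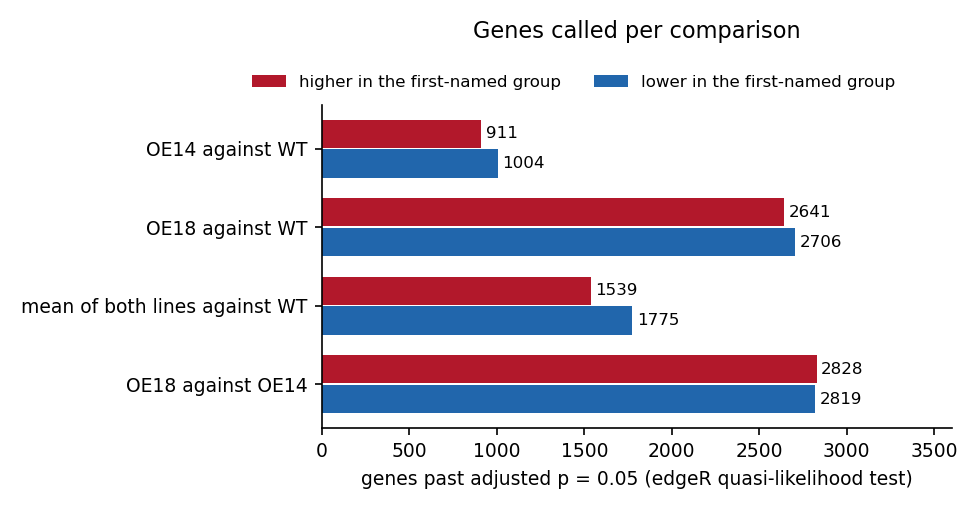
Genes called by edgeR's quasi-likelihood test at an adjusted p under 0.05 (horizontal, number of genes) in each of the 4 comparisons (vertical), split into genes higher (red) and lower (blue) in the first-named group. OE14 against WT has 911 and 1004 calls, and OE18 against OE14 has 2828 and 2819.

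In the genes called in both lines, 405 were higher and 381 lower than WT in OE14 and in OE18, which is 786 genes with the same direction, and 125 were called in opposite directions. Independent lists of the same sizes would share 96.5 higher and 108.9 lower genes, and 205.2 in opposite directions. The shared genes made up 41% of the OE14 calls and 14.7% of the OE18 calls. By position, 45 of the shared higher genes lay in the chromosome 13 region, 32 of the shared lower genes in the chromosome 5 region and 19 in the chromosome 7 region, and 354 higher and 329 lower ones lay outside the shifted regions. Without OE14 replicate 2 the lines shared 514 calls.

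Both comparisons use the same WT libraries, which ties their fold changes together without any effect. Over all tested genes, the log2 fold changes of the lines had a Pearson correlation of 0.33 and a Spearman correlation of 0.30, with 60.9% of genes of the same sign; these are correlations across genes, which are not independent replicates. In 50 simulations of unchanged groups that share WT libraries, the mean correlation was 0.50, the mean share of the same sign 66.5%, and at most 1 gene was called in both lines with the same direction. The observed covariance was 0.164, against a simulated mean of 0.0283 (0.0259 to 0.0314), a difference of 0.135. Outside the shifted regions the covariance was 0.165. The WT libraries were not split between the lines, since 3 of them would leave 1 for a line, so part of the excess of shared calls may come from the shared controls.

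The comparison of OE18 with OE14 asks whether the lines differ from each other. The chromosome 5 region was higher in OE18, with a median log2 fold change of 0.94, a ratio of 1.92, and 249 of 255 expressed genes on that side. The chromosome 18 region was lower, with a median of -0.58, a ratio of 0.67, and 118 of 124 genes on that side. The 20 genes of the chromosome 2 region had a median of -0.59. The segment statistics were 31.4, 14.0 and 6.6, against a highest permuted value of 5.74. The chromosome 7 and 13 regions had medians of 0.05 and -0.01 between the lines.

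The lines differed in 5647 genes (22.6%) in edgeR's quasi-likelihood test, 2828 higher and 2819 lower in OE18, with 1072 and 765 of them at least 2-fold. Of the 786 genes called in both lines with the same direction, 186 (23.7%) also differed between the lines. Of the 1004 genes called in OE14 only, 772 (76.9%) differed between the lines, as did 3077 of the 4436 called in OE18 only (69.4%), and the remaining genes of these sets are not shown to differ. All 125 genes called in opposite directions differed. Runs of neighbouring 2-fold calls were higher in OE18 at 5 genes of chromosome 13 (11030711 to 11479976, median 2.80), 4 genes of chromosome 16 (12783031 to 12814790, median 2.74) and 6 genes of chromosome 1 (40412588 to 40618695, median 2.99). They were lower in OE18 at 6 genes of chromosome 12 (739831 to 965929, median -5.40), 4 genes of chromosome 17 (15815003 to 15930686, median -4.52) and the 4 genes of chromosome 6 that were higher in OE14 against WT (27283823 to 27459671, median -4.96). In all, 154 neighbouring pairs were found against a permuted mean of 55.0 and a highest value of 78 (p = 0.001 in 1000 permutations, the smallest they can give). Fitted fold changes of genes at or near a count of 0 in a group depend on the prior count, so the medians of these short runs carry that limit.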

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

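The regions and the on and off genes were found in the data before they were tested. The bounds for the chromosome ends were set after their median shifts had been seen, and were then applied to each chromosome separately. The quartiles and the share of genes on the side of the shift were computed together with the medians. The bounds therefore cannot be taken as set blind to the spread between genes. For the on and off genes, the tests of an effect common to both lines and of differences between founder plants were chosen only after the result was seen. The bounds of the other tests were set before their values were computed. Groups of 3 libraries are too small for a test of outlying libraries.

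The effects of the lines against WT differed between the lines, by the test of the difference itself, in 5647 genes. Among them were 125 genes that were called higher in a line and lower in the other. They also include 257 genes of the chromosome 5 region that were higher in OE18 than in OE14, 99 genes of the chromosome 18 region that were lower and 12 genes of the chromosome 2 region that were lower, counting all tested genes of the regions.

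The first pattern is the shift of the ends of chromosomes 5 and 18 in OE14. Regulation of part of the neighbouring genes is argued against, since 96.9% of the chromosome 5 genes and 90.3% of the chromosome 18 genes lay on the side of the shift by at least 0.3. Loss or gain of reads from a diverged haplotype would make the change uneven from gene to gene. In OE14 against WT, the interquartile range on chromosome 18 was 0.78 times that of other genes, which argues against this cause there. On chromosome 5 it was 1.26 times, between the bounds set for and against this cause, which cannot be told apart there. In OE18 against OE14, the range was 0.371 in the chromosome 18 region, against 0.366 for other genes. In the chromosome 5 region it was 0.457, against 0.364 for other genes. An altered copy number remains as a candidate explanation, as a hypothesis: at least 76.9% of the chromosome 5 genes lay within 0.5 of a log2 ratio of -1.0 (a copy ratio of 0.5) and at least 87.1% of the chromosome 18 genes within 0.5 of 0.58 (a copy ratio of 1.5), in OE14 against WT and against OE18, compared with 4.4% and 30.3% of all scanned genes in OE14 against WT. The regions, their medians and the spread of their genes came from the same fold changes, so these tests were not independent of the pattern. No DNA was measured.

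The second pattern is a set of 43 genes that were on in every library of some group and off in every library of another, with the remaining group also fully on or fully off. Genes with a remaining group in between were not counted. WT stood alone in 8 of them, all on in WT and off in both lines; OE14 stood alone in 12 (5 on, 7 off) and OE18 in 23 (13 on, 10 off). An effect of the transgene common to both lines would leave WT standing alone, which was so in 18.6% (95% exact binomial interval 8.4% to 33.4%). In the other genes the lines differed from each other, so such an effect by itself does not describe the whole set. The bound of 50% was chosen after this share was seen. The interval treats genes as independent and is too narrow where neighbours move together, so no verdict is drawn from it. Loss or gain of larger segments cannot be told apart: 46.5% of the genes (31.2% to 62.3%) had a nearest neighbour that moved the same way by at least 0.5, between the bounds of 25% and 50%, where all tested genes would give 8.2 of 43 genes. Differences between the plants that founded each group, genetic or epigenetic, stay open. Each group stood alone in 8 or more genes here. With on set at 10 CPM, WT stood alone in 4 of 21 genes (off below 0.5 CPM) and 4 of 24 (off below 1 CPM), under the bound of 5. That bound is a fixed count and harder to reach in a smaller set, so it cannot decide the question. Reads lost at a variant were not tested.

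The third pattern is the set of calls shared by both lines. Chance values of the shared WT libraries are argued against as its whole cause. The covariance of the fold changes was 0.164 and the highest of 50 simulations 0.0314. The lines shared 786 calls where a simulation gave at most 1. The simulated groups held no effects, so few calls of any kind could arise there, and that count cannot decide the question. Covariance grows with the size of the fold changes. The correlation of 0.33 and the same-sign share of 60.9% lay below the simulated means of 0.50 and 66.5%. Effects of a single line widen the fold changes and lower both values, and the simulation held none. The correlation and the same-sign share therefore cannot decide for or against that cause. Traits of the WT plants unrelated to LbDREB6 would give shared calls as well. With a single WT source such traits and an effect of the transgene are confounded, and neither was tested alone.

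Other splits of the same libraries bear on whether the counts of calls could arise from any grouping. With 3 libraries against 3 there are 10 splits, too few for a share under 0.05: 1 of 10 splits gave as many calls in each of the 3 pairwise comparisons, the real one, with 1915 calls in OE14 against WT (highest other split 0), 5347 in OE18 against WT (1) and 5647 in OE18 against OE14 (0). For the mean of both lines and for the shared calls, 100 splits of the 9 libraries were used. As many genes came from 2 of 100 splits for each, the real one included, a share under the bound of 0.05. Splits that mix libraries of different groups raise the spread within the made-up groups, which lowers their counts. The share therefore shows that libraries differ by group. It cannot decide whether WT stands apart from the lines in particular: set against the mean of the other groups, OE14 differed in 3221 genes and OE18 in 6620. The real values were 3314 and 786, and the other split gave 4412 and 2399. That split took the 3 OE18 libraries as the control, so it follows a real group and points to the distance of OE18 from the rest; the next highest gave 480 and 189.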

How the results depend on the processing

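The settings were listed before the data were examined, except the refits without the shifted regions, those of the region medians and the other limits for on and off, which were chosen after seeing the data. The counts of calls stayed within 1.5 times their main value under other scalings, other filters, the DESeq2 Wald test, limma-voom and, where it applies, a fit on only the groups compared. Fitted on only the groups compared, OE14 against WT rose from 1915 to 2372 calls, while OE18 against WT fell from 5347 to 4101. OE18 against OE14 fell from 5647 to 5225. DESeq2 gave no adjusted p for 3754 to 4379 genes, which were counted neither way. With an added 2-fold threshold the counts were 781 for OE14 against WT, 1727 for OE18 against WT, 849 for the mean of both lines, 1837 for OE18 against OE14 and 287 shared by both lines, as the threshold by construction removes smaller changes. Leaving out a library gave 1240 to 2571 calls for OE14 against WT (1240 without OE14 replicate 2, 1261 without OE14 replicate 1), 3944 to 5675 for OE18 against WT, 2035 to 4243 for the mean of both lines (2035 without WT replicate 2, 2199 without WT replicate 3), 4017 to 5826 for OE18 against OE14 and 514 to 1038 shared calls (514 without OE14 replicate 2). Each upper end except that of OE18 against OE14 came without OE18 replicate 1. The cause of these shifts was not tested. Without the genes of the 5 shifted regions, 1324, 5079, 2769 and 5121 genes were called in the same order of comparisons, and 627 were shared. The 4 named genes kept their direction and stayed under an adjusted p of 0.05 in 60 of 60 refits (largest adjusted p 0.000305). The medians of the regions that were shifted in a comparison kept their sign under the other scalings, filters and tests, in the fits on only the groups compared and without any library; medians near 0 were not refitted. Over the 213 genes of the chromosome 13 region, the median of 0.374 in OE14 and 0.356 in OE18 against WT became 0.271 and 0.266 without WT replicate 3, and 0.461 and 0.451 without WT replicate 2. Limits other than 5 and 0.5 CPM gave 21 to 96 on and off genes. The tests of gene lists were not run, since no gene had a description. No paired analysis was run, because the labels give the groups no shared replicate numbers. Depth limits genes with few counts, as in WT for the 2 named genes that rose.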

Other observations

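The comparison of the WT libraries with windows elsewhere in the genome and the ranking of genes by spread were chosen after the values were seen. At the first end of chromosome 13 the WT libraries differed from each other as well as from the lines. Against the mean of the 6 transgenic libraries, the region stood at ratios of 0.78, 0.88 and 0.68 in WT replicates 1, 2 and 3, with 194, 161 and 200 of its 213 expressed genes below that mean. WT replicate 3 was below WT replicate 2 in 196 of 213 genes (92%), by a median of 0.35 on the log2 scale (log2 difference -0.35). The SD of the 3 WT libraries was 0.187, against a median of 0.014 and a highest value of 0.033 over 80 windows of 213 neighbouring genes outside the shifted regions. In the same region the SD was 0.018 in OE14 and 0.027 in OE18. On chromosome 7 the WT libraries stood at 1.57, 1.44 and 1.39 times the mean of the transgenic libraries.

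Some abundant genes varied several-fold between libraries of the same group. The 3 such genes at 14788312 to 14795129 on chromosome 13 together had 2570, 960 and 3210 CPM in WT replicates 1 to 3, 1540, 2200 and 6560 CPM in OE14, and 699, 1520 and 5170 CPM in OE18. Their range within a group was 3.3-fold in WT, 4.3-fold in OE14 and 7.4-fold in OE18. Replicate 3 had the highest value in each group. Among the other genes with a large spread, some also had replicate 3 highest in each group, and others had it lowest in OE18. The labels do not say whether libraries of the same number were handled together, and this was not tested. The median within-group SD of genes with a mean of at least 20 CPM was 0.12 on the log2 scale.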
